A study of Mus musculus with 12 samples.

How the data were processed

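MicroRNA (miRNA) levels were measured in 12 libraries from male NOD mice, an inbred strain that develops autoimmune diabetes, at postnatal day 23. The labels give ileum as the tissue, and the series' design text speaks of RNA from intestinal epithelial cells, so the share of other cell types in the samples is not settled by the sources. Per the labels' protocols, total RNA was isolated with a column kit and prepared for the NanoString nCounter miRNA assay with the mouse panel of version 1.5. In this assay each mature miRNA is ligated to a tag, hybridised to a coloured reporter and counted without amplification. The labels place 4 libraries in a control group, 4 in an antibiotic group and 4 in a group given cecal material. They do not say whether the mice given cecal material had also received the antibiotic. All libraries carry the same batch label. Dams with their litters were randomised to the groups, and no dam or litter is given per library, so p-values measure the spread between libraries that could come from the same litter.

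The deposited table holds normalised signal for 599 probes, of which 566 name mouse miRNAs and 33 name herpesvirus miRNAs. It lists no positive, negative or housekeeping control probes, and the software and scaling behind the values are not given in the sources used here. Every deposited signal was a whole count multiplied by 1 factor per library, 100% of the values being whole within 0.01 of a count. The sums over the 100 most abundant probes lay between 219892 and 220585 in all libraries, while the recovered totals did not. The recovered total count ranged from 120235 to 393551 per library, and 1 count was worth between 0.590 and 1.92 units of signal. The signal of 32 used as the background limit corresponded to 16.6 counts in the shallowest library and 54.2 counts in the deepest. The lowest recovered count was 1 in every library, with no zeros.

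Because the values are scaled counts, the count model foreseen for a table of raw counts was not the main test. Signal was transformed to log2(value + 1), and a mouse probe was tested if it exceeded 32 in at least 4 libraries, which left 226 probes. Log2 fold changes are on this scale and understate the change of weak probes. One linear model over the 12 libraries was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean level. The 3 pairwise comparisons and a moderated F test were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Values are group means ± SD (n = 4). Fold changes come from the model, with standard errors (SE).

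Lists of miRNAs were fixed before the data were examined, 22 in all, covering cell types, families, genomic clusters and responsive groups. Probes were matched by miRNA name with arm suffixes ignored. The 16 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, repeated with an estimated correlation, and with fry. Camera compares a list with the other miRNAs, whereas fry asks whether the members of a list move on balance in one direction. The rule for named miRNAs, also fixed beforehand, took for each comparison up to 12 called miRNAs of largest change in each direction. Where fewer than 10 passed, it took the 10 of smallest p as values. It also took up to 4 tested members of highest mean per list and the 10 most abundant miRNAs. Other miRNAs are named below as called members of a list, as the few calls of an alternative, or because they were singled out after their values were seen, as stated there.

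Separation of the groups was the share of squared Euclidean distance lying between them, tested over all 35 splits of 8 libraries, or with 100000 permutations for the 3 groups. Totals per library were compared with exact two-sided permutation tests, for which 0.0286 is the smallest p that 4 libraries against 4 can give. For shared controls, unchanged groups were simulated 1000 times. Replicates of 1 group, which are separate animals and so vary by more than counting noise, had a chi-square per degree of freedom of 2.96 to 29.8 on the recovered counts, and their log2 signals correlated at 0.968 to 0.995 across probes.

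The fit was tested on simulated data modelled on cecal transfer against control, with 226 probes of which 60 were changed, in 20 runs. It recovered 40.5% of the 1.25-fold changes, 78.8% of the 1.5-fold changes and 93.2% of the 2-fold changes. Of the calls, 3.66% were unchanged probes.

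Alternatives fixed beforehand were median centring, quantile normalisation, TMM factors, a pseudocount of 10, no filter, a filter of 100, other variance moderation, array weights, fits of only the groups compared, an estimated correlation for lists and each library left out in turn. The alternatives chosen after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered counts, thinning to the shallowest library, background subtraction, log2 depth as a covariate, and removal of 4 probes high in control replicate 3. Figures were drawn with matplotlib 3.10.9.

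Probes of near-identical family members, such as let-7 or miR-23a and miR-23b, can share signal on a hybridisation assay, and 4 tested probes name more than 1 miRNA. Which miRNA genes lie within 10000 bases of each other was taken from the RefSeq annotation of GRCm38.p6, which matched 212 of the 226 tested probes by name. The deposited table names no genome build, so no coordinates are given. The herpesvirus probes stayed out of the counts of miRNAs and served as a measure of background, for which they were compared between groups with limma on their own.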

Results

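The data are miRNA levels in the ileum of 12 male NOD mice at postnatal day 23, with 4 libraries each from control mice, mice given antibiotic and mice given cecal material (cecal transfer). The most abundant probe was miR-145, a miRNA typical of smooth muscle and fibroblasts, with a mean over all libraries of 24186 units of normalised signal. It was followed by miR-720, let-7g, the enterocyte miRNA miR-194, miR-143, miR-16, let-7c, let-7d, the endothelial miRNA miR-126-3p and let-7f. The tested miRNAs included members of the lists for epithelial, muscle, endothelial and blood cell types.

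Depth differed between the groups. The recovered total count was 215929 ± 43689 (SD, n = 4) in control, 136539 ± 12394 in antibiotic and 327366 ± 52206 in cecal transfer libraries, and the ranges of the groups did not overlap. The exact permutation p was 0.0286 for each pair, the smallest possible, and 0.0286 after adjustment over the 3 pairs. Differences between groups accounted for 87.4% of the variance of log2 depth. After the scaling in the deposited table, the total over mouse probes was 232330 ± 2622 in control, 232246 ± 1009 in antibiotic and 231564 ± 451 in cecal transfer libraries. These totals did not differ beyond the spread, with exact p = 0.943, 0.943 and 0.314 for antibiotic against control, transfer against control and transfer against antibiotic. They could hardly differ, as the sums over the 100 most abundant probes lay between 219892 and 220585 in all libraries. These tests therefore say nothing on the amount of miRNA in the samples. Over the tested probes alone, the total was higher in cecal transfer than in antibiotic libraries by 701, with exact p = 0.0286 and 0.0857 after adjustment over the 3 pairs.

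**Figure D1:**
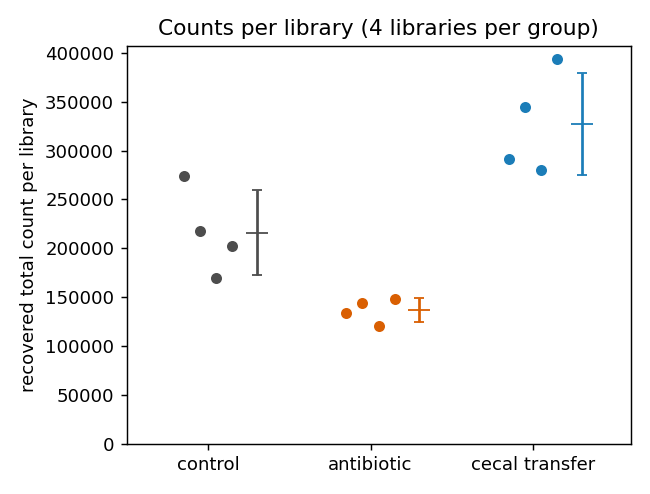
Recovered total count of each library (points) by group, with the group mean and SD (bar, n = 4). The antibiotic libraries lie between 120235 and 148297 and the cecal transfer libraries between 280114 and 393551, on either side of the controls.

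The first comparison asked what the antibiotic changed in the miRNAs of the ileum. No miRNA differed between antibiotic and control libraries past the threshold. The smallest adjusted p was that of miR-181c, a member of the lymphocyte miR-181 family, with 96.7 ± 3.97 in antibiotic and 64.8 ± 10.1 in control libraries (log2 fold change 0.58, SE 0.12, adjusted p = 0.0647). miR-1, a striated muscle miRNA, had 763 ± 266 against 1351 ± 308 (log2 −0.85, SE 0.21, adjusted p = 0.0781). miR-1968 had a log2 difference of 0.70 (adjusted p = 0.0781), miR-125b-5p of 0.34 and miR-27b of 0.44 (both adjusted p = 0.0965). The other miRNAs of smallest p were miR-350 (log2 −0.39), miR-196b (−1.72), miR-2134 (−2.34), the probe for miR-466a-3p and miR-466b-3-3p (0.89) and miR-191 (0.25), all at adjusted p = 0.119.

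With limma, 0 of 226 miRNAs passed in this comparison and 34 had an unadjusted p under 0.05, against 11.3 expected by chance. edgeR on the recovered counts also called 0, and DESeq2 called 3, namely miR-1, miR-196b and miR-2134. The values of miR-196b and miR-2134 rested in large part on control replicate 3. Without that library their log2 differences were −1.02 and −1.44. Without control replicate 4, 8 miRNAs passed, and without control replicate 1, 3 did.

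Over the lists fixed beforehand, none shifted past the threshold after antibiotic. The let-7 family came nearest, with 8 of 9 members lower by a median log2 of −0.09 (camera p = 0.00436, adjusted p = 0.0697, and adjusted p = 0.909 with an estimated correlation). None of its members passed, either over all miRNAs tested or adjusted over the list alone. The 5 members of the miR-200 family, which maintain epithelial identity, had a median log2 of 0.06, and the enterocyte miRNAs miR-192 and miR-194 had −0.03 and −0.20. Adjusted over the list alone, 1 member passed in each of 6 lists: miR-7a (log2 0.32) among secretory and endocrine miRNAs, miR-181c among leukocyte miRNAs, miR-1 among striated muscle miRNAs, the erythroid miR-144 (0.36), miR-497 (0.53) of the miR-15/16 family and miR-27b of the miR-23/27/24 clusters.

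The second comparison asked how the ileum of mice given cecal material differed from that of untreated mice. Of 226 miRNAs, 68 differed, 41 higher and 27 lower. The enterocyte miRNA miR-194 fell from 12337 ± 3666 in control to 6478 ± 963 in cecal transfer libraries (log2 −0.89, SE 0.18, adjusted p = 0.00183), while the smooth muscle miRNA miR-145 rose from 19976 ± 2622 to 30024 ± 3588 (log2 0.59, adjusted p = 0.000437). miR-10a, encoded within a Hox gene cluster, rose 3.08-fold, from 331 ± 77.6 to 1004 ± 64.8 (log2 1.62, SE 0.18, adjusted p = 2.45e-05). miR-125b-5p rose 1.93-fold, from 2316 ± 253 to 4472 ± 413 (adjusted p = 6.63e-06), and miR-23b fell 2.01-fold, from 1206 ± 256 to 591 ± 52.5 (adjusted p = 0.00017).

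The largest rise was that of miR-322, of the miR-15/16 seed family, 3.85-fold from 123 ± 55.4 in control (log2 1.94, SE 0.29, adjusted p = 0.000281). miR-301b rose from 40.5 ± 3.72 to 118 ± 3.73 (log2 1.52) and miR-130a, which shares its seed, from 173 ± 25.2 to 341 ± 40.1 (log2 0.98). Of the same seed, miR-130b (0.10, adjusted p = 0.738) and miR-301a, both added after the values were seen, did not pass. Other leading rises were those of miR-377 (1.58), miR-762 (1.50), miR-764-3p (1.43), the myosin-gene miRNA miR-499 (1.31), miR-367 (1.27), miR-2146 (1.01) and miR-369-3p (0.99). Most of these lay near background in control libraries, with means of 18.5 for miR-377, 21.5 for miR-762 and 17.6 for miR-367. Below control were miR-1968 (−1.19), miR-490 (−0.93), miR-3471 (−0.86), miR-2140 (−0.86), miR-2132 (−0.57), miR-93 (−0.51), miR-141 (−0.49) and miR-139-5p (−0.47). miR-2134 (−1.99) and miR-2141 (−1.17) also passed, but each lost its call in 10 of the 12 fits with a library left out, and without control replicate 3 their log2 changes were −1.10 and −0.62. miR-499 and miR-367 each lost it in 3 of the 12.

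Among the miRNAs of the 2 main epithelial lists, those that passed were all lower. In the miR-200 family 3 of 5 members fell, namely miR-141, miR-200c (log2 −0.31) and miR-429 (−0.28), whereas miR-200a (−0.03) and miR-200b (−0.02) did not pass. The family was lower than other miRNAs by camera (adjusted p = 0.0482, and adjusted p = 0.483 with an estimated correlation). Both enterocyte miRNAs fell, miR-194 as above and miR-192 by 0.29 on the log2 scale. Of the secretory and endocrine miRNAs, miR-7a rose (0.36) and miR-375 had −0.11. The sensory-epithelium cluster had no member past the threshold (median −0.06).

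Among the lists for other cell types, most members did not pass, and more of those that did were higher than lower. Of 5 smooth muscle and fibroblast miRNAs, miR-145, miR-143 (log2 0.18) and miR-199a-3p (0.29) rose and miR-10b (−0.36) fell. Of 9 leukocyte miRNAs 3 rose, namely miR-142-5p (0.53), the activation-linked miR-155 (0.42) and miR-181a (0.39), while the abundant miR-142-3p (0.15), the myeloid miR-223 (−0.04) and miR-150 (0.13) did not pass. Of 3 erythroid miRNAs miR-144 (0.69) and miR-486 (0.75) rose and miR-451 had 0.28. The liver miRNA miR-122 rose (0.41). Of the endothelial pair, miR-126-5p fell (−0.41) and the far more abundant miR-126-3p had −0.05. None of 6 neural miRNAs passed, nor did the pancreatic miR-216b (0.09), and of 3 striated muscle miRNAs only miR-499 did, with miR-1 at −0.17 and miR-133a at 0.02. None of these lists passed by camera (adjusted p = 0.368 for smooth muscle and fibroblast, 0.281 for leukocyte and 0.104 for erythroid). By fry the smooth muscle and fibroblast, leukocyte and erythroid lists did pass (adjusted p = 0.00849, 0.00849 and 0.00505).

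Families showed both shared and opposed changes. In the miR-17-92 cluster and its paralogs, a proliferation-linked group, 5 of 8 probes fell, namely those for miR-20a and miR-20b (log2 −0.39), miR-17 and miR-106a (−0.33), miR-25 (−0.30), miR-106b (−0.29) and miR-93 (camera adjusted p = 0.0266, and adjusted p = 0.483 with an estimated correlation). In the let-7 family, linked to differentiation, let-7i (−0.34) and let-7d (−0.18) fell, 7 of 9 did not pass, and the family's camera adjusted p was 0.0482 (adjusted p = 0.483 with an estimated correlation). In the miR-23/27/24 clusters miR-27b (0.88), miR-24 (0.73), miR-27a (0.30) and miR-23a (0.23) rose while miR-23b fell. In the miR-29 family miR-29a (0.22) and miR-29c (0.39) rose and miR-29b (−0.28) fell. miR-30c (0.45) rose alone among 5 members of the miR-30 family. Of 6 members of the miR-15/16 family only miR-322 rose. Of the NF-kappaB-responsive list miR-155 and miR-146b (0.49) rose, and miR-21 (−0.20) and miR-146a (0.09) did not pass. In the imprinted Dlk1-Dio3 cluster miR-369-3p and miR-377 rose, miR-329 (−0.33) and miR-434-3p (−0.39) fell, and 15 of 19 did not pass. Neither miR-34b-5p (−0.09) nor the hypoxia-responsive miR-210 (0.04) passed.

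With a library left out, the let-7 family lost its camera call in 8 of 12 fits and the miR-200 family in 6, while the miR-17-92 group kept it in all 12. Adjusted over the list alone, the counts for this comparison were those given above, except that all 3 erythroid miRNAs were higher. By fry, 8 of the 16 lists moved in one direction on balance. The split of 41 higher and 27 lower depended on the processing, being 28 and 28 with median centring and 26 and 27 with quantile normalisation. It was 34 and 36 over all mouse probes without a filter, and 20 and 3 with log2 depth in the model. Median centring ended the calls of miR-143 (adjusted p = 0.365), miR-199a-3p (0.129), miR-155 (0.0598), miR-122 (0.0978), miR-7a (0.104), miR-29a and miR-23a (both 0.290) and turned none of them. With log2 depth in the model 23 of the 68 calls held, among them miR-10a, miR-322, miR-125b-5p, miR-27b, miR-141 and miR-194. The 5 falls of the miR-17-92 group and those of let-7i, let-7d, miR-200c, miR-429 and miR-192 kept their sign but lost their calls. miR-23b went from −1.01 to −0.53 (SE 0.17, adjusted p = 0.0636) and miR-145 from 0.59 to 0.43 (SE 0.15, adjusted p = 0.0827) with that covariate. Thinning all libraries to the shallowest kept 56 of the 68.

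**Figure D2:**
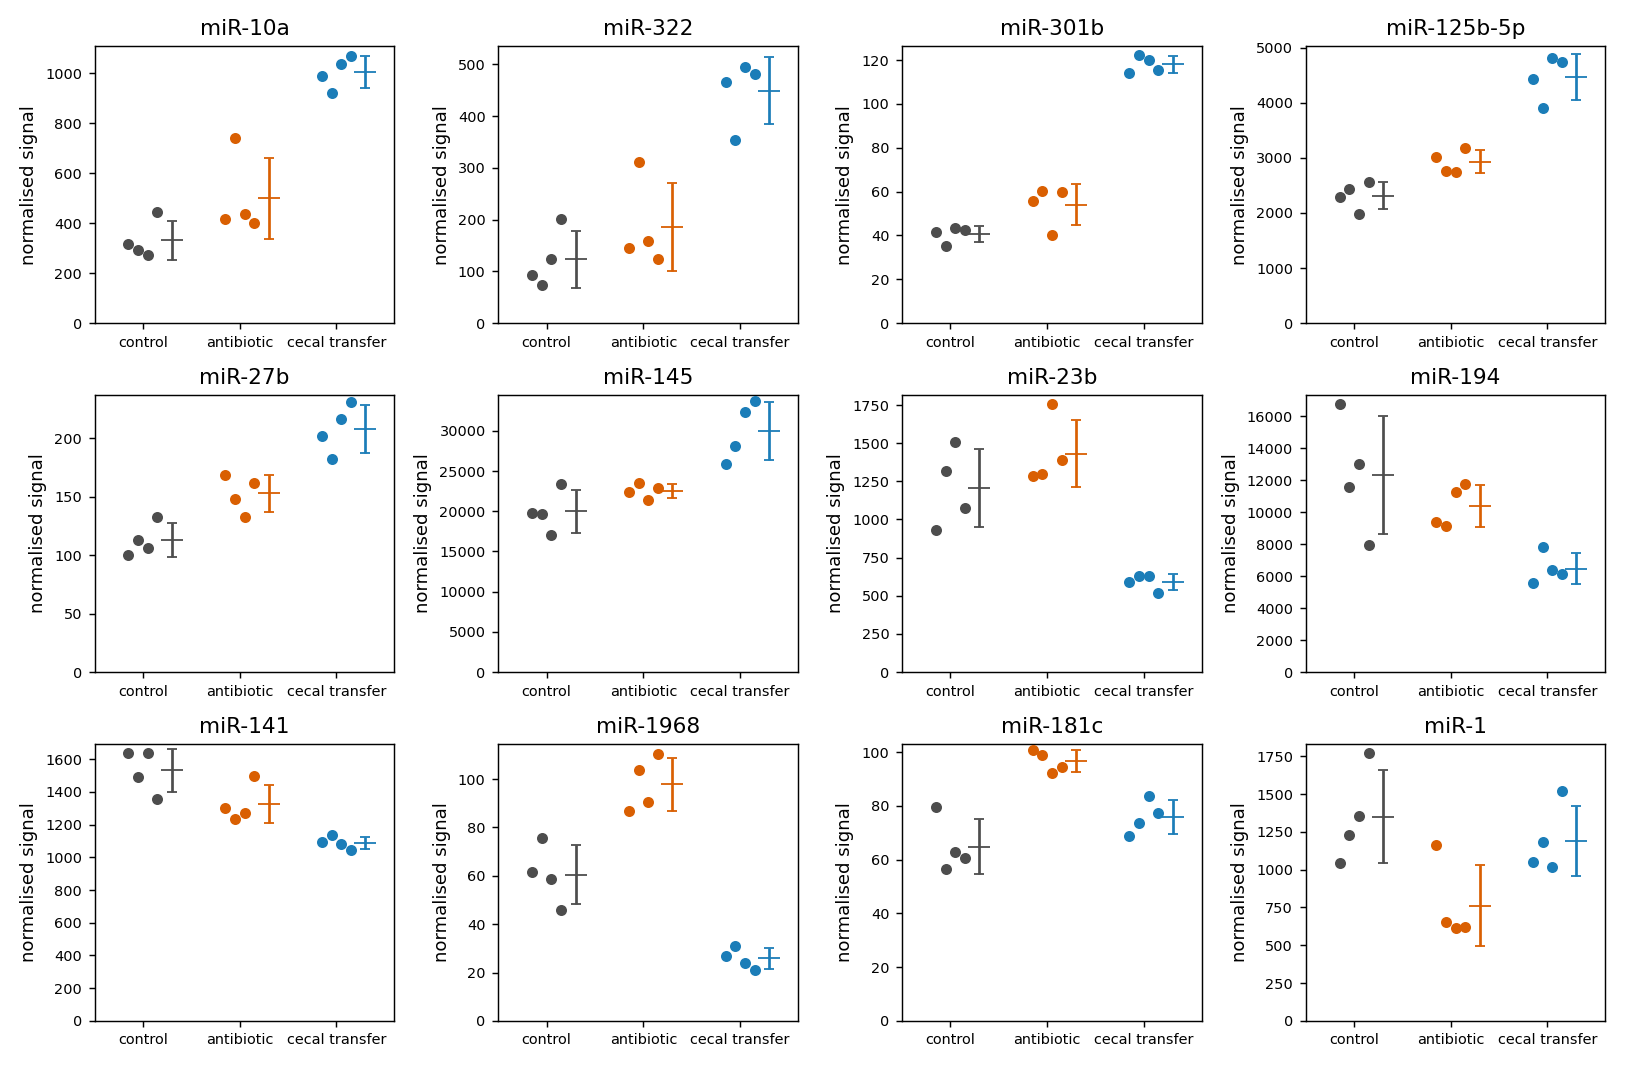
Normalised signal of 12 miRNAs in each library (points), with group mean and SD (bar, n = 4); the axes are linear and start at 0. In the cecal transfer libraries miR-10a, miR-322, miR-301b and miR-125b-5p lie above every control and antibiotic library, and miR-23b and miR-1968 lie below.

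The third comparison asked how cecal transfer differed from antibiotic. Of 226 miRNAs, 74 differed between these libraries, 45 higher and 29 lower in cecal transfer. Of the 33 herpesvirus probes, which measure background, 9 passed in the same comparison. miR-10a was 2.07-fold higher (log2 1.05, SE 0.18, adjusted p = 0.000837), miR-322 2.56-fold (log2 1.35, SE 0.29) and miR-301b 2.19-fold (log2 1.13, SE 0.14). miR-1968 was 3.70-fold lower (log2 −1.89, SE 0.17, adjusted p = 5.66e-06), and miR-23b had −1.27 (adjusted p = 4.22e-05). miR-194 was again lower (−0.69, adjusted p = 0.0108) and miR-145 higher (0.41, adjusted p = 0.00606).

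The other leading rises were those of miR-367 (log2 1.63), miR-2146 (1.32), miR-377 (1.20), miR-764-3p (1.17), miR-362-3p (1.00), miR-369-3p (0.96), miR-3472 (0.90), miR-32 (0.88) and miR-762 (0.87). With a library left out, miR-762 lost its call in 7 of 12 fits, and miR-421 and miR-497, both lower, in 4 and 1. Below antibiotic were miR-490 (−1.62), miR-2140 (−1.17), miR-3471 (−1.02), miR-128 (−0.89), miR-421 (−0.70), miR-139-5p (−0.63), miR-2132 (−0.57), miR-497 (−0.55) and miR-200c (−0.48). miR-1 was higher in cecal transfer than in antibiotic libraries (0.68, adjusted p = 0.022), and miR-181c was lower (−0.35, adjusted p = 0.0385). miR-21, an inflammation-induced miRNA, was lower as well (−0.46, adjusted p = 0.00141).

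In the miR-17-92 group 5 of 8 probes fell and miR-18a (0.62) rose (camera adjusted p = 0.0371, and adjusted p = 0.499 with an estimated correlation). miR-200c, miR-429 (−0.35) and miR-141 (−0.28) fell, with the miR-200 family at camera adjusted p = 0.0647. miR-192 (−0.26) missed the threshold over all miRNAs and passed adjusted over the list alone. Of the smooth muscle and fibroblast miRNAs miR-145, miR-143 (0.21) and miR-199a-3p (0.33) rose, with 4 rises adjusted over the list alone. miR-142-5p (0.50), miR-155 (0.50), miR-181a (0.35) and miR-150 (0.21) rose and miR-181c fell among 9 leukocyte miRNAs, and all 3 erythroid miRNAs rose, namely miR-486 (0.61), miR-451 (0.34) and miR-144 (0.33). Neither the leukocyte (camera adjusted p = 0.439), the smooth muscle and fibroblast nor the erythroid list (both 0.368) passed by camera, while by fry each did (adjusted p = 0.0128). let-7i (−0.21) was the only let-7 member to pass. In the miR-23/27/24 clusters miR-24 (0.76), miR-27b (0.44) and miR-27a (0.30) rose and miR-23b fell. Adjusted over the list alone, miR-23a also rose (0.17), as did miR-216b (0.35), and the miR-15/16 family had 1 rise and 2 falls. By fry, 5 of the 16 lists moved in one direction on balance. The split was 22 higher and 32 lower with median centring and 23 and 28 with quantile normalisation, and 50 and 111 over all mouse probes without a filter. With median centring miR-145 (adjusted p = 0.0702), miR-143, miR-199a-3p and the 3 erythroid miRNAs lost their calls, and with log2 depth in the model no call was left. With that covariate 72 of 74 kept their sign, the median change in the direction called went from 0.50 to 0.60 and the median SE from 0.141 to 0.392, though miR-23b went from −1.27 to −0.29.

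**Figure D3:**
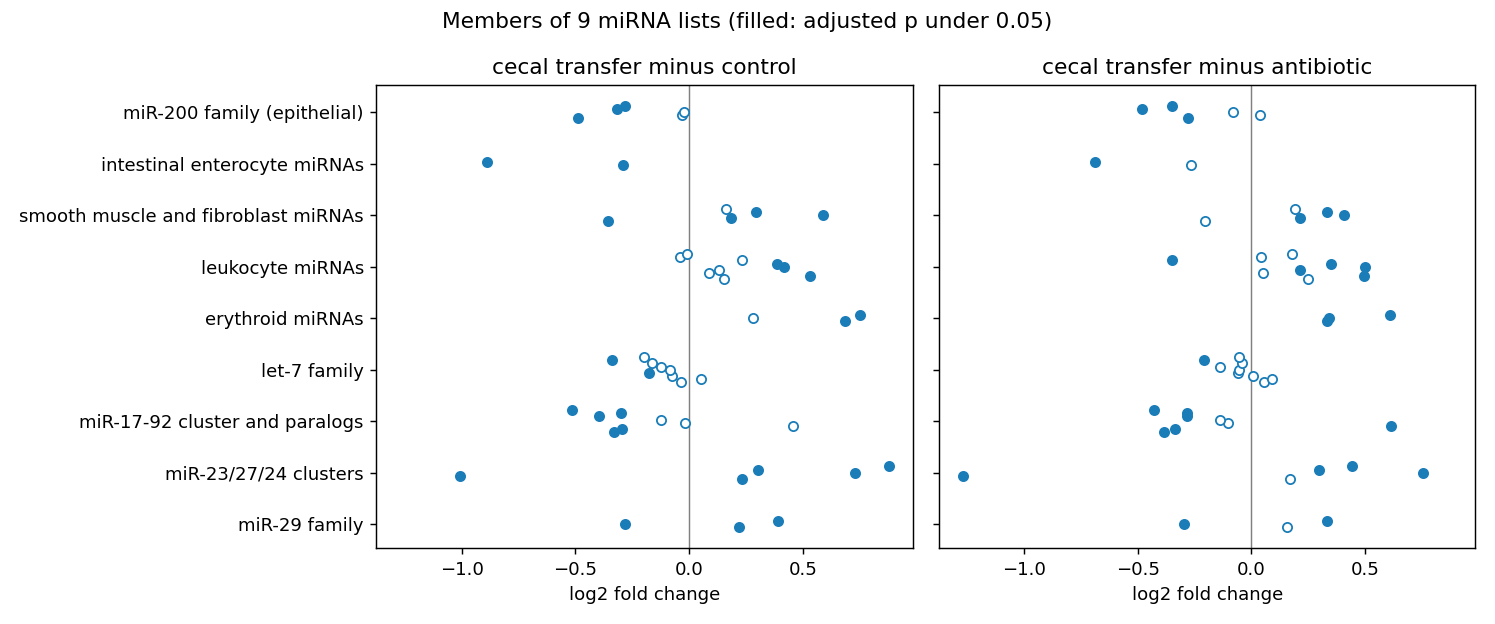
Log2 fold change of each tested member of 9 miRNA lists, for cecal transfer against control (left) and against antibiotic (right); filled points passed an adjusted p of 0.05. All filled points of the miR-200 family and the enterocyte miRNAs lie below 0, and those of the erythroid miRNAs above 0.

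The calls of the 2 cecal transfer comparisons overlapped. miRNAs higher in both numbered 33 and miRNAs lower in both 22, with 0 in opposite directions. Independent lists of these lengths would share 8.16 and 3.46. Unchanged groups set against the shared transfer libraries gave 0.004 and 0.002 shared calls. As nothing differed between those groups, few calls could arise, so these values do not measure the overlap that shared libraries create. With the transfer libraries split between the comparisons, 11 to 19 were shared among the higher and 5 to 8 among the lower over 6 splits. The F test over the 3 groups called 73 of 226.

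Over all tested miRNAs, 51.0% of the squared distance between libraries lay between the 3 groups (permutation p = 0.00027). Between pairs it was 28.9% for antibiotic and control, 48.6% for cecal transfer and control, and 53.9% for cecal transfer and antibiotic, each with exact p = 0.0286, the smallest that 35 splits allow. The first principal component, with 37.2% of the variance, parted the transfer libraries from the rest. The second, with 25.6%, lay mainly in control replicate 3, at −7.15, with the other libraries between −1.50 and 3.22.

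The series' title asks whether cecal transfer undoes the effect of the antibiotic. Since no miRNA passed in antibiotic against control, the 20 of smallest p were followed, as planned. In 8 of them the cecal transfer mean lay between the antibiotic and control means, among them miR-181c, with 75.9 ± 6.22 between 96.7 and 64.8, miR-1, with 1191 ± 230 between 763 and 1351, and miR-191. Another 4 of the 8, miR-196b, miR-2134, miR-1186 and miR-376b, were probes high in control replicate 3 alone. In 7 it lay beyond the antibiotic mean, away from control, as for miR-10a, miR-125b-5p, miR-27b, miR-301b and miR-144. In 5 it lay past control on the other side, as for miR-1968, with 25.8 ± 4.19 against 60.4 in control and 97.9 in antibiotic libraries, miR-490 and miR-21.

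The share of the antibiotic difference undone had a median of 0.450, a value that has meaning only if the cecal transfer mice had also received the antibiotic, which the labels do not say. Picking miRNAs by their antibiotic difference favours such a return. Simulated unchanged groups gave 74.0% of means in between on average, against 40% observed, and a share of 0.001 of the runs was at or below that. In the simulation probes varied independently and cecal transfer did not differ from control, whereas 68 miRNAs differed here. Such changes put means outside the interval whatever the antibiotic did, so the lower share of means in between does not tell for or against a return. The share depended on single libraries: without control replicate 1 it was 65%, against a mean of 75.6% in simulations of the same 11 libraries, and a share of 0.185 of those runs was at or below that. Across miRNAs, which are not independent replicates, the differences of the 2 groups from control had a covariance of 0.0733, against a mean of 0.0178 in simulated unchanged groups, a difference of 0.0554. The highest of the 1000 simulated values was 0.0365. That difference fell to 0.0139 without the 4 probes high in control replicate 3 and turned to −0.0520 without a filter, so the covariance of the antibiotic and transfer differences from control rested on the probes included. The correlation was 0.43 (0.50 in simulation), and with split controls the covariance was 0.0284 to 0.0770. Without control replicate 3, 10 of 20 means lay in between, the median share undone was 0.740 and the covariance was 0.0388.

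**Figure D4:**
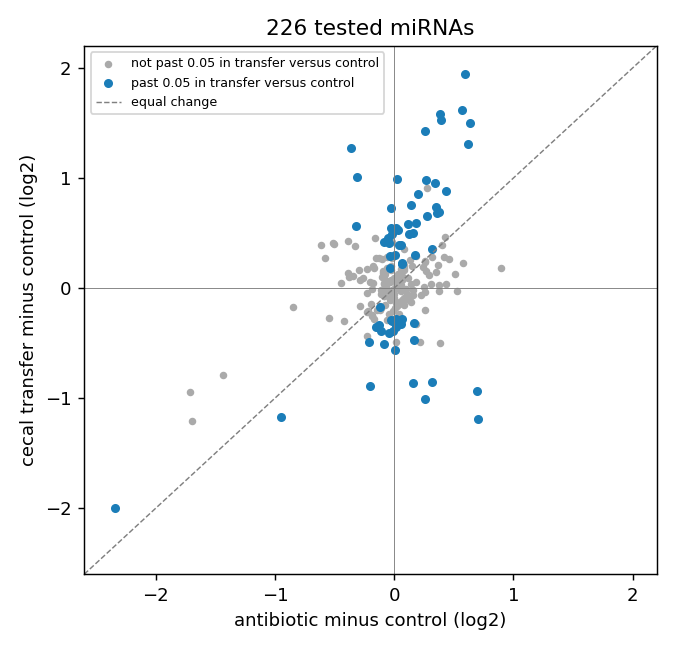
Log2 difference from control of each of the 226 tested miRNAs in antibiotic (horizontal) and cecal transfer (vertical) libraries; blue points passed in cecal transfer against control. Of those 68, 41 lie above 0 on the vertical axis and 27 below.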

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

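The tests of depth (with the covariate, by thinning and over splits of the controls), background and epithelial share and the remark on litters were chosen after the results were seen, and the counts over other splits of the libraries were not.

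A library stood apart from the other 3 of its group, by a gap large against the group's range, in 20 of 312 groups of values, where chance, at about 1 in 20, gives 15.6. After antibiotic, miR-1 stood at 1162 in replicate 1 (next 651), miR-377 at 13.9 there (next 27.6), miR-10a at 741 in replicate 2 (next 438), miR-2132 at 119 (next 144) and miR-25 at 1920 (next 2158) there, the probe for miR-466a-3p and miR-466b-3-3p at 32.7 in replicate 3 (next 47.2), let-7c at 7111 (next 6585) and miR-223 at 810 (next 335) there, and miR-124 at 56.7 in replicate 4 (next 76.3). After cecal transfer, replicate 1 had miR-466a-3p and miR-466b-3-3p at 15.1 (next 29.8), miR-367 at 63.4 (next 38.1) and miR-451 at 1579 (next 1205). Replicate 2 had miR-223 at 934 (next 336), miR-137 at 75.5 (next 84.0) and miR-17 with miR-106a at 2157 (next 1916). Replicate 3 had miR-369-3p at 119 (next 109) and replicate 4 had miR-7b at 57.2 (next 69.8). In control, replicate 3 had miR-30a at 406 (next 432) and miR-27a at 2900 (next 2655), and replicate 4 had let-7f at 6240 (next 5218). Without antibiotic replicate 1, miR-1 passed in antibiotic against control, with a log2 difference of −1.07.

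Chance assignment of libraries to groups is argued against for the counts of both transfer comparisons and of the F test. For a pair, 1 of 35 splits is the smallest share possible. The splits treat libraries as independent, which shared litters would break. The 68 calls against control were reached by 1 of 35 splits, the real one, with 3 as the highest other, and the 74 calls against antibiotic by 1 of 35, with 1 as the highest other. The 73 calls of the F test were reached by 1 of 100 splits, with 62 as the highest other. For antibiotic against control the splits say nothing on chance, since a count of 0 is reached by all 35 whatever the data (highest other 1). The separation of that pair, 28.9%, was the highest of its 35 splits (exact p = 0.0286), but missed the threshold without a filter (17.1%, exact p = 0.171). It also missed the threshold in each of the 4 fits without an antibiotic library. Fits without a cecal transfer library use the same libraries of this pair, so they could not change its separation. For the same pair limma, edgeR and DESeq2 gave 0, 0 and 3 calls, with 34 miRNAs at an unadjusted limma p under 0.05. For lists, the 3 shifts in cecal transfer against control were reached by 1 of 35 splits (highest other 2) and the 1 against antibiotic by 5 of 35 (highest other 1). Chance is thus argued against for the former and not for the latter. That holds for the preset correlation alone, since 0 lists passed with an estimated one, and the 3 shifts dropped to 1 in 6 of 12 fits with a library left out. The 0 list shifts after antibiotic are again reached by all 35 splits by construction (highest other 1).

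For the miRNAs that differed between cecal transfer and control, a background that adds the same to every probe of a library is argued against. After subtraction of each library's herpesvirus mean, 68 of 68 calls held in direction. Background that differs from probe to probe was not tested and stays open. Of the 33 herpesvirus probes, mcmv-miR-M23-1-5p (log2 −1.25) and mcmv-miR-m108-2-5p.1 (−0.99) passed in this comparison, and the others did not. A smaller epithelial share that lowers all 8 epithelial miRNAs alike is argued against as the whole cause, because their changes were unequal (exact p = 0.0286, the smallest possible). miR-141 had a 95% interval of −0.66 to −0.32 and miR-200a one of −0.22 to 0.15. The 8 come from lists for different epithelial cells, so a shift in the mix of those cells could give unequal changes and stays open. A linear trend with depth as the whole cause is argued against for the 23 calls that held with log2 depth in the model, and an unequal number of counts sampled for the 56 that held after thinning to the shallowest library, 33 of them not among the 23. For the other 45 a linear trend with depth stays open. The median change of the 68 was 0.54 without and 0.53 with the covariate, while the median SE went from 0.141 to 0.226. The opposite movement predicted in the shallow antibiotic libraries was seen in some splits of the controls and not in others (signed median −0.0239 to 0.145). What else goes with depth, such as RNA input, cannot be told apart from group for any of the 68. Differences between groups accounted for 87.4% of the variance of log2 depth. Shared litters cannot be told apart from group either, as 0 libraries carry a dam or litter label, and an effect of the cecal material stays among the open explanations.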

How the results depend on the processing

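The tests with edgeR, DESeq2, thinned counts, background subtraction, the depth covariate and without the 4 probes high in control replicate 3 were chosen after the results were seen. DESeq2 was foreseen for a table of raw counts and was run on the recovered counts instead, as the table holds scaled ones.

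Of the 24 miRNAs named as called in cecal transfer against control, 8 were tested and passed under all 28 settings and 13 under all but the depth covariate. Another 11 were too weak for the filter of 100. Against antibiotic, where 13 of 24 were too weak for that filter, 11 were tested and passed under all but the covariate, and none passed with it, the median change of the calls going from 0.50 to 0.60 and the median SE from 0.141 to 0.392. All kept their direction except miR-2141 against control, at 0.030 with depth as covariate. That covariate left 23 calls against control, 0 against antibiotic and 27 in the F test. Thinning to the shallowest library left 56 and 62 calls. Without a filter, 161 passed against antibiotic, 50 higher and 111 lower, and 129 in the F test. For antibiotic against control the count of 0 became 2 with quantile normalisation (miR-1 and miR-181c), 1 without a variance trend (miR-181c), 3 with DESeq2, and 0 to 8 with a library left out. The separation of these groups was 17.1% without a filter (exact permutation p = 0.171) and 27.8% to 35.5% with a library left out. It missed the threshold in each of the 4 fits without an antibiotic library (exact p = 0.0857). Fits without a cecal transfer library could not change it, as they use the same libraries of this pair. List shifts after antibiotic numbered 1 with TMM, without a filter, with the filter of 100 and without the 4 probes, and 0 to 1 with a library left out. Against control they fell to 1 with quantile normalisation, the filter of 100 and thinning, 0 with an estimated correlation and 1 to 3 with a library left out. Against antibiotic they were 0 with median centring, quantile normalisation, an estimated correlation and without the 4 probes, 2 with TMM and background subtraction, 3 without a filter and 0 to 2 with a library left out. The share of means between antibiotic and control was 35% to 65% with a library left out. The covariance of the antibiotic and transfer differences from control, beyond its simulated mean, reversed to −0.0520 without a filter, and was 0.0842 after background subtraction, 0.0139 without the 4 probes and 0.0202 to 0.0961 with a library left out. The total signal of cecal transfer minus antibiotic libraries was −682 over all mouse probes, 701 over tested ones and −1177 to −431 with a library left out. The cause of these changes was not tested.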

Other observations

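The comparison of neighbouring miRNA genes, the sum of miR-23a and miR-23b and the choice of miRNAs named in this part were made after the results were seen, as were the tests of control replicate 3 that set its 4 high probes against depth and against evenly added background. The test on the share of weak probes was not.

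Related miRNAs outside the lists also differed in cecal transfer against control. miR-100 (log2 0.58, adjusted p = 0.00175) and miR-125a-5p (0.73, adjusted p = 0.000281) rose, as miR-125b-5p did, while miR-99b (−0.11), whose gene lies beside that of miR-125a, did not pass. Neither did miR-99a (−0.27, adjusted p = 0.368) nor miR-125a-3p (0.03, adjusted p = 0.917). miR-101b (0.54) rose in both transfer comparisons and miR-101a (0.82, adjusted p = 0.0108) against antibiotic.

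Of 119 pairs of tested probes whose genes lie within 10000 bases, 17 had both members called in cecal transfer against control, 13 in the same direction and 4 in opposite directions. Among the former were miR-362-5p (0.85) with miR-532-5p (0.54), miR-143 with miR-145, miR-192 with miR-194, miR-141 with miR-200c, and miR-25 with miR-93 and with miR-106b. The opposed ones were miR-23b with miR-27b, miR-23b with miR-24, and miR-29b with miR-29a and with miR-29c. The miR-24 probe matches a gene beside miR-23b and another beside miR-23a and miR-27a, so it also counts among the pairs in the same direction. The miR-29b probe likewise matches a gene beside miR-29a and another beside miR-29c. The signal of these probes cannot be assigned to either gene.

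The fall of miR-23b beside the rise of its neighbours miR-27b and miR-24 was weighed against shared signal with the near-identical miR-23a. miR-23a rose from 2338 to 2742 while miR-23b fell from 1206 to 591 against control, and their sum went from 3544 ± 293 to 3333 ± 120 (exact two-sided permutation p = 0.257), which leaves a trade of signal between the probes open. Against antibiotic the sum fell from 3874 ± 267 (exact two-sided p = 0.0286, the smallest possible). That would argue against a trade only if the probes were equally efficient, which is not known. The weight of miR-23b picked for the highest p was 0.36 (exact p = 1). Since miR-23a was higher and miR-23b lower, some weight levels the sums whatever the cause, so this cannot decide. A trade stays open there too. Across all neighbouring pairs the median difference in change was 0.311, against 0.338 after shuffling (permutation p = 0.327), so it stays open whether miRNAs of neighbouring genes move together here at all. With log2 depth in the model, the change of miR-23b went from −1.01 to −0.53 against control (limma adjusted p = 0.0636). Against antibiotic it went from −1.27 to −0.29 (limma adjusted p = 0.605). A trend with depth therefore stays open for miR-23b as well. Different processing or stability of the mature forms is a biological alternative that was not tested.

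Control replicate 3 held 4 probes, miR-1186, miR-196b, miR-2134 and miR-376b, at 4.57 to 7.28 times the highest other control. Even added background as the whole of it is argued against, since the rise of mouse probes that did not pass the filter had a 90th percentile of 12.8 units, while the smallest rise among the 4 probes was 316. Low depth is argued against too, since the 4 probes averaged 3.54 log2 units more than in the highest antibiotic library, all of which are shallower. A general rise of weak probes stays open. Of the 340 mouse probes that did not pass the filter, 55.6% were highest in this library among the controls. Over all 340 the median ratio to the mean of the other controls was 1.43. The herpesvirus probe mghv-miR-M1-7-5p stood at 426 against 69.1 to 185 in the other controls. No biological explanation was tested.

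Of the 33 herpesvirus probes, a measure of background, some differed between groups. In limma, 2 passed in cecal transfer against control, both lower, and 9 against antibiotic, of which only mcmv-miR-M87-1 was higher (log2 0.89). In antibiotic against control 0 passed, with 3 at an unadjusted p under 0.05. Of the 226 mouse miRNAs, 68 passed in cecal transfer against control and 74 against antibiotic. Against antibiotic the share of herpesvirus probes was not far below that of miRNAs, so the number of calls there does not by itself set miRNAs apart from background. Only 2 of the 33 herpesvirus probes exceeded 32 in at least 4 libraries. Their mean, without mghv-miR-M1-7-5p, was 11.3 ± 2.55 in control, 12.2 ± 1.80 in antibiotic and 8.92 ± 0.805 in cecal transfer libraries, and did not differ past the threshold (exact p = 0.0571 for cecal transfer against either group, 0.0857 after adjustment, and 0.543 for antibiotic against control).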
